A study of Escherichia coli with 12 samples.

How the data were processed

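RNA of 2 strains of Escherichia coli DH1 was hybridised together on 12 spotted arrays, the FPP-accumulating strain with the plasmids pMBIS and pADSmut against the amorphadiene producer with pMBIS and pADS. Per the labels, cells grew in M9 medium and were induced near an optical density of 0.3 with IPTG (0.5 mM) and fed mevalonate (20 mM). The design text, per the labels, gives 1 biological replicate; a condition was hybridised to 2 arrays, or to 4 at regular MgSO4 14 h. Whether the times of a medium share a pair of cultures is not given in the sources used here. An earlier sampling time mentioned in the series' design text was not analysed here. Each array carried 4289 loci at 3 spots per gene, among 13872 spots in 48 print blocks, of which 1005 are named empty or blank.

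The deposited scanner tables hold, per the file headers, the median intensity of each spot and of its local background at both scan wavelengths, with no background subtraction or normalisation, and the background's standard deviation as an intensity. Each table also gives the percent of saturated pixels per spot, per the file headers, and a quality score deposited by the scanner software, in which negative values mark bad, absent or missing spots. Per the file headers, GenePix Pro 6.0 made 8 tables and GenePix Pro 6.1 made 4. The authors' deposited value table holds log2 ratios of the FPP strain over the amorphadiene strain; its unit and direction were found by setting each column against that array's own scanner ratios (Pearson's r across genes 0.987 to 0.999, slope 0.941 to 1.07). Its columns have medians from -0.0163 to 0.0219, and how they were normalised is not given in the sources used here. It has 4288 entries, 1 of them not in the scanner tables, and was used as an alternative.

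Which dye each strain carried was taken from the labels. In low MgSO4 at 10 h the FPP strain carried Alexa555 and the ratios were turned; in the other 4 conditions it carried Alexa647. Of the gene spots, 2.45% to 31.8% per array were marked bad by the scanner software. These and empty positions had weight 0 in the normalisation, and marked spots were left out of averages. With limma 3.58.1 in R 4.3.3, background was corrected by normexp with an offset of 50, log2 ratios were normalised within arrays by global loess (span 0.3), and the spots of a gene were averaged. A gene was kept where a channel exceeded background by 2 background SDs on at least 0.5 of the arrays, which kept 4120 and removed 169. Arrays had a value for 3219 to 4117 genes. The number of arrays limits the precision. Labels were read with jsonlite 2.0.0.

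Gene symbols came from a RefSeq table of assembly ASM584v2, used for names only. By locus tag 4120 of 4289 loci matched, and 169 kept the array's own name. A spot was called saturated with more than 50% of its pixels saturated, and a gene in a strain where most of its spots were saturated on every array of the condition; no fold is given then.

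The arrays of a condition were averaged to 1 value, giving 5 values per gene. The mean ratio over conditions was tested against 0 with limma's lmFit and eBayes over 3946 genes, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The medium and time coefficients came from a fit over the 4 conditions at 10 and 14 h with both terms. Genes at least 2-fold different on every array of a condition were counted without a test. Gene lists were tested by camera with a correlation of 0.01 and with an estimated correlation, and by fry. With an estimated correlation camera uses only the fit's few residual degrees of freedom (1 for medium and time), which leaves it little power. In each condition a list's median was set against 10000 random lists matched on intensity in 10 bins. Of 43 lists, 42 were tested and 1, with fewer than 4 measured genes, was left out; 840 of 846 distinct genes named in the lists were found on the array.

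The groups, tests, lists, the alternatives to be tried and the rule for named genes were chosen before the data were examined. By that rule, genes past the threshold with the same sign in all conditions are named first; where a direction has fewer than 5 of them, the 8 largest means with the same sign in all conditions are given as values. Each condition contributes the 4 highest and 4 lowest genes among those 2-fold different, the medium and time comparisons the 4 highest and 4 lowest coefficients when none passes, and each list up to 4 members with the same sign in all conditions. A few genes, among them idi, ispA, dxs, lacZ, phoP, mgtA, rpoS, marA, soxS and pspA, are named whatever their values. The list tests for medium and time, and fits restricted to a medium or to the earlier-scanned arrays, were added after the data were seen.

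The procedure was tested on simulated data with known changes. With the real spread between conditions, the test over all conditions recovered 65.7% of genes changed 1.5-fold. It recovered 95.5% of those changed 2-fold and 98.5% of those changed 4-fold. It also called 9 of the 3745 genes outside its own changed set. Some of these carried simulated medium or time changes, so this is no count of false calls. The medium and time tests recovered 0 genes at that spread at any of these sizes, and 88.1% to 100% at 0.25 of it. That spread, each gene's SD over the 5 conditions, includes any real medium and time differences and may overstate the noise of these fits. The changed list was called and 0 of 20 random lists were. Simulated genes varied independently, while called lists in the real data had estimated correlations up to 0.717. The simulation therefore cannot show how often lists of correlated genes are called falsely. Its changed genes were drawn at random, whatever their spread between conditions. In the real data yqjF, aroF and raiA had means past 2-fold and did not pass. The recovered shares may therefore be too high for real changes. Alternatives covered background correction, normalisation within and between arrays, the dim filter, marked spots, the choice of spot, the authors' values, each array and condition left out, a dye term, blocks and fold limits.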

Results

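Transcripts of Escherichia coli DH1 were compared between a strain that accumulates farnesyl diphosphate (FPP), a precursor of terpenes, and a strain that makes the terpene amorphadiene from it. Both strains carry a plasmid with a mevalonate pathway (pMBIS); the second plasmid is pADSmut in the FPP strain and pADS in the amorphadiene strain. Each of 12 arrays of 2 colours held RNA of both strains, so every ratio is FPP strain over amorphadiene strain. The arrays fell into 5 conditions of M9 medium, sampled after mevalonate and IPTG were added. Medium labelled low MgSO4 was sampled at 10, 14 and 26.5 h with 2 arrays each, and medium labelled regular MgSO4 at 10 h with 2 arrays and at 14 h with 4 arrays. The design text gives 1 biological replicate, so the arrays of a condition were taken as technical repeats of 1 pair of RNA samples and averaged. Across genes, Pearson's r between arrays of a condition was 0.828 to 0.952 with 2 arrays and 0.363 to 0.764 at regular 14 h. The second regular 14 h array had 0.694 and 0.705 with the regular 10 h arrays. The growth protocol in the labels gives 10 mM MgSO4 for the medium named low and 2 mM for the medium named regular, against those names, so the groups are named by label. Median spot signal was 3.12 to 28.7 times the median local background, the lowest being the fourth regular 14 h array. The SD between arrays of a condition had a median over genes of 0.06 to 0.07 on the log2 scale for the conditions with 2 arrays and 0.14 at regular 14 h. In low MgSO4 at 10 h the FPP strain carried the opposite dye to that in the other 4 conditions.

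The first comparison asked which transcripts differed between the FPP strain and the amorphadiene strain whatever the medium and time. glcF (b2978), named for a subunit of glycolate oxidase, rose in the FPP strain by a mean log2 ratio of 1.81 (SE 0.15, adjusted p = 0.0199 by limma) and was positive in 5 of 5 conditions, from 1.18 at regular 10 h to 2.20 at low 10 h. npr (b3206), a phosphocarrier of the nitrogen-related phosphotransferase system, rose by 0.77 (SE 0.08, adjusted p = 0.0275) and was positive in 5 of 5 conditions, between 0.60 and 0.92. No gene was lower past the threshold. The array's b2978 is an older locus that the annotation now lists as a synonym of both glcF and glcE, so the spot can name either gene.

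Beyond these 2 genes, values are given without a call. yqjF had a mean of 1.59 (SE 0.21, adjusted p = 0.0787 by limma) and stood between 0.78 and 2.38. aroF, which encodes an enzyme that starts aromatic amino acid synthesis, averaged 1.36, and rseB, a regulator of the envelope stress factor sigma E, averaged 1.15. ygiS averaged 1.09, bamA, an essential factor of outer membrane protein assembly, 1.08, yhcN 1.03 and bhsA 1.02. In the other direction, the ribosome hibernation factor gene raiA averaged -1.37 and the zinc-binding protein gene zinT -0.91. The iron-sulfur regulator gene iscR averaged -0.90, fimA, the main subunit of type 1 fimbriae, -0.83, and glpA, a glycerol 3-phosphate dehydrogenase subunit, -0.83. The regulator genes ycgZ, ydeO and ymgA averaged -0.81, -0.78 and -0.77.

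Of 3946 genes with a value in every condition, 376 were higher and 486 lower in the FPP strain in all 5, together 21.8%, where 5 independent signs would give 6.25%. The moderated test in limma passed 2 genes, both higher, and 889 genes had an unadjusted p under 0.05 (413 higher, 476 lower), against 197.3 by chance. These p-values measure only the spread between conditions, which share the same strains, and each condition has 1 biological replicate. No gene passed without low 10 h, low 14 h, low 26.5 h or regular 14 h (smallest adjusted p 0.113, 0.131, 0.175 and 0.0820), and only glcF passed without regular 10 h (adjusted p = 0.00740). A dye term left 0 genes: glcF had 1.96 (SE 0.18) and npr 0.74 (SE 0.10), against 1.81 (SE 0.15) and 0.77 (SE 0.08) without it, and the larger errors, with 1 fewer degree of freedom, gave adjusted p = 0.121 for both. In turn, scaling between arrays gave 11 (7 higher, 4 lower), scan day as a random block 26 (8 higher, 18 lower) and 12 arrays with condition as a random block 144 (91 higher, 53 lower). The scan day fit had 6 values in 4 blocks. In it regular 14 h, 1 biological replicate, entered once per scan day, so both the values and the block differ from the main fit.

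**Figure D1:**
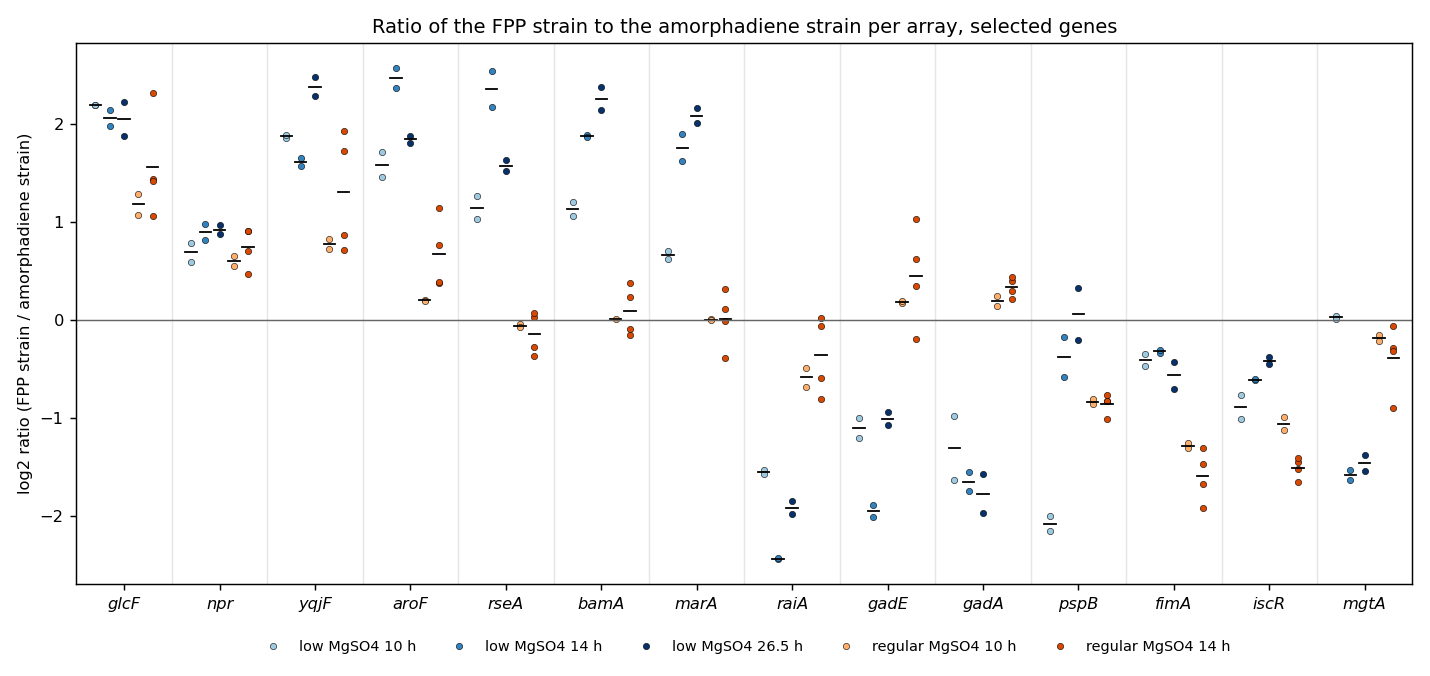
Log2 ratio of the FPP strain to the amorphadiene strain for 14 selected genes, 1 point per array and a bar at each condition's mean; colours give medium and time. glcF and npr lie above 0 in every condition, while rseA, bamA and marA have condition means of 0.66 or more in low MgSO4 and between -0.14 and 0.09 in regular MgSO4.

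Gene lists fixed before the data were examined were then tested over all conditions. The sigma E envelope stress regulon had the highest mean log2 ratio of the lists called, 0.57 over 19 genes, and 8 of its genes were higher in all 5 conditions, but neither this list nor any other passed with a correlation estimated from the data (adjusted p = 0.732 with an estimated correlation). The genes named from these lists had the same sign in all 5 conditions; here they were rseB (1.15), bamA (1.08), rseC (0.78) and bamB (0.72), which encode sigma E regulators and outer membrane assembly factors, and rseA had 0.98 without that. The 53 ribosomal protein genes averaged 0.34, with rpsB (0.75), rplW (0.65), rplC (0.58) and rplV (0.58). Genes of the MarA-SoxS-Rob regulon, which respond to drugs and redox stress, averaged 0.27, with marA at 0.90 and fumC at 0.58. The median of its 16 genes was lower, 0.15. At low 26.5 h, where its mean was highest (0.43), 8 genes were above 0 and 8 below, against 13 and 3 at regular 14 h. Fatty acid and phospholipid synthesis genes averaged 0.17, with the acetyl-CoA carboxylase genes accC (0.73) and accA (0.27). Iron acquisition genes averaged 0.10, with exbD at 0.41 and exbB at 0.30.

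Lower means were found for acid resistance genes of the Gad system and for curli and type 1 fimbriae, by the same test that gave none with an estimated correlation (adjusted p = 0.732). The Gad list averaged -0.37 over 13 genes; its members below 0 in all conditions were dctR (-0.40) and yhiD (-0.39). The curli and fimbriae list averaged -0.25 over 16 genes. No gene of that list passed over all genes tested, and 5 did, all lower, adjusted over the list alone: fimA, fimI (-0.67), csgF (-0.49), csgE (-0.46) and csgB (-0.46). In the other 6 lists called no gene passed either way.

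By limma's camera test with a preset correlation of 0.01, 7 of 42 lists passed: sigma E (adjusted p = 2.16e-05), ribosomal proteins (adjusted p = 5.36e-05), MarA-SoxS-Rob (adjusted p = 0.00892), curli and fimbriae (adjusted p = 0.0134), Gad (adjusted p = 0.0165), fatty acid synthesis and iron acquisition (adjusted p = 0.0396 each). None of the 7 passed camera with a correlation estimated from the data (adjusted p = 0.732 with an estimated correlation, for each). This form rests on the fit's few residual degrees of freedom, so failing it does not show that gene correlation removes a call. For MarA-SoxS-Rob the estimated correlation was -0.04, below the preset 0.01. Its unadjusted p by camera still rose from 0.000637 to 0.0215. By limma's fry test, which asks whether a list's genes move 1 way on balance, MarA-SoxS-Rob (adjusted p = 0.00936) and the outer membrane porins (adjusted p = 0.00233, mean -0.16) passed. The Gad call ended without low 14 h (-0.21, adjusted p = 0.108) or low 26.5 h (-0.28, adjusted p = 0.168), and turning the sign of some conditions gave up to 10 lists. The fatty acid synthesis call ended without low 10 h (mean 0.17, adjusted p = 0.0923), low 14 h (0.13, adjusted p = 0.0523) or low 26.5 h (0.09, adjusted p = 0.357), and the iron acquisition call without low 14 h (0.06, adjusted p = 0.111), regular 10 h (0.10, adjusted p = 0.0720) or regular 14 h (0.09, adjusted p = 0.106).

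Medians of the sigma E, ribosomal and Gad lists were not alike in the 2 media. The median of the sigma E list was 0.36, 1.02 and 1.33 in low MgSO4 at 10, 14 and 26.5 h, above all of 10000 random lists matched on intensity, and 0.01 and 0.05 in regular MgSO4 at 10 and 14 h. In low MgSO4 at 26.5 h all 20 of its measured genes were above 0 and 15 were at least 2-fold higher on both arrays. Ribosomal protein genes had medians of 0.70, 0.65 and 0.88 in low MgSO4 and -0.18 and -0.21 in regular MgSO4. The Gad list had medians of -0.19, -1.0 and -0.66 in low MgSO4 and 0.18 and 0.32 in regular MgSO4. The curli and fimbriae list had its lowest medians in regular MgSO4, -0.26 at both times.

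**Figure D2:**
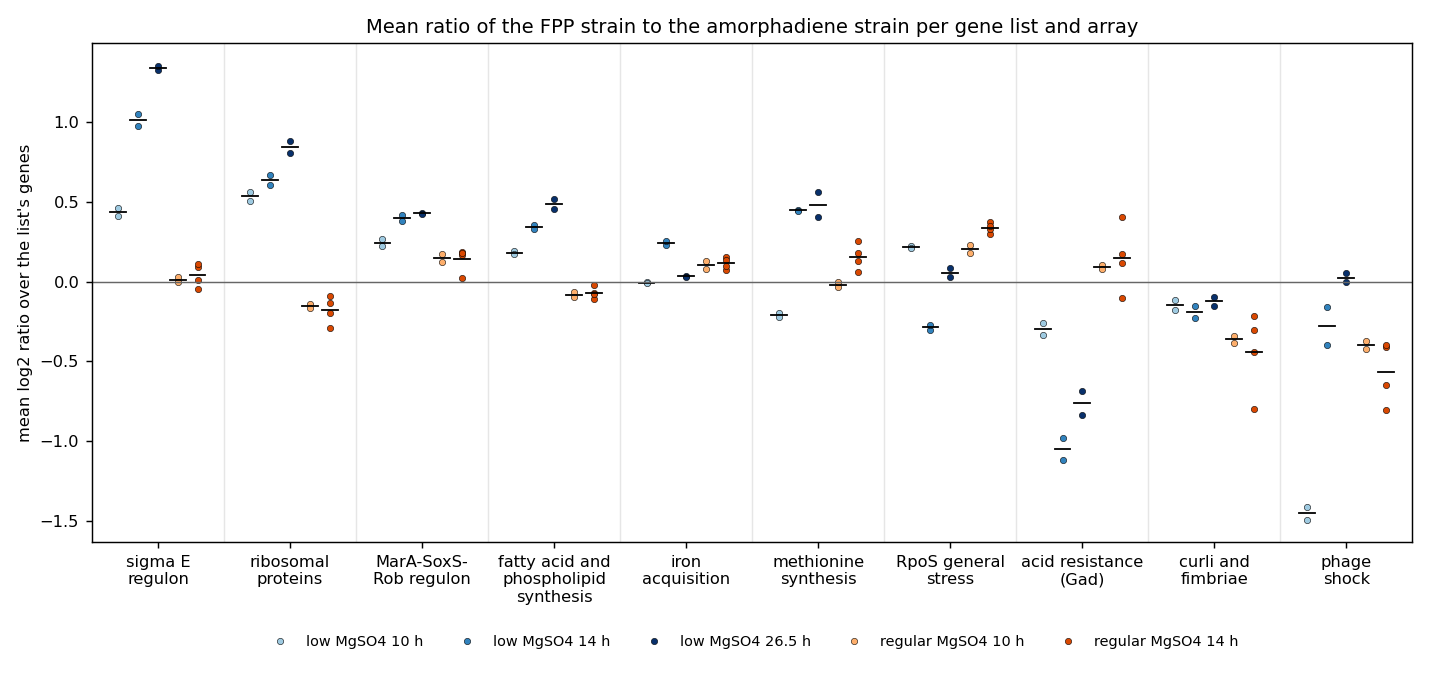
Mean log2 ratio (FPP strain over amorphadiene strain) of 10 gene lists, 1 point per array and a bar at each condition's mean; colours give medium and time. Sigma E and ribosomal protein genes are high in the 3 low MgSO4 conditions (list means from 0.42 to 1.33) and between -0.17 and 0.04 in regular MgSO4, and the phage shock list is lowest at low 10 h (-1.45).

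Each condition was also described by the genes at least 2-fold different on every one of its arrays, which covers technical error only and carries no test. In low MgSO4 at 10 h, 53 genes met this, 35 higher and 18 lower. The highest were glcF (2.20), yqjF (1.88), bhsA (1.84) and yhcN (1.72). The lowest were 4 genes of the phage shock operon, which responds to damage of the inner membrane: pspA (-2.16), pspB (-2.08), pspD (-1.99) and pspC (-1.93). At the other times in this medium pspB had ratios of -0.38 and 0.06. In regular MgSO4 the phage shock list was also low, with medians of -0.46 at 10 h and -0.76 at 14 h. At 14 h and 26.5 h the pspA spots of the FPP strain were saturated, as were those of pspD and pspE at 26.5 h, and no fold is given for them.

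At 14 h in low MgSO4, 209 genes were 2-fold different, 102 higher and 107 lower, but with scaling between arrays 46 were, 27 higher and 19 lower, against 91 at low 10 h and 86 at low 26.5 h. aroF (2.47), rseB (2.45), rseA (2.36), the anti-sigma factor of sigma E, and proV (2.23), a subunit of a glycine betaine transporter, were highest. raiA (-2.44), yiaG (-2.29), the acid resistance regulator gadE (-1.95) and the taurine transport gene tauC (-1.82) were lowest. At 26.5 h the genes numbered 123, and 114 of them were higher. yqjF (2.38), mltD (2.35), a murein transglycosylase, bamA (2.26) and ygiM (2.11) were highest. gadB (-1.96), raiA (-1.92), gadA (-1.78) and glgS (-1.50) were lowest. gadA and gadB are near-identical copies of glutamate decarboxylase, so their spots can share RNA.

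In regular MgSO4 fewer genes reached 2-fold. At 10 h there were 6: osmE (1.23) and glcF (1.18) higher, and fimA (-1.29), fimI (-1.25), yejB (-1.20) and the insertion sequence gene insF5 (-1.12) lower; copies of insertion sequences can share RNA. At 14 h there were 5: glcF (1.56) higher, and fimA (-1.59), iscR (-1.51), yehI (-1.51) and phnN (-1.21) lower. Leaving out either array at regular 10 h gave 10 and 16 genes, and using only the first 2 arrays at regular 14 h gave 9.

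Low 14 h and low 26.5 h shared 64 higher genes, where 2.93 would be shared by independent lists; with scaling between arrays only 27 are higher at low 14 h, so no more could be shared. Without that scaling, as for the other values here, all 9 genes lower at 26.5 h were lower at 14 h (0.240 by chance). Among the shared higher genes were rpoE, rseA, rseB and rseC of sigma E, ribosomal protein genes such as rplF and rpsE, the RNA polymerase gene rpoA, and marA and marB. glcF was the gene shared by all pairs of conditions among those higher. Across genes, which are not independent replicates, Pearson's r between conditions was 0.291 to 0.589 within low MgSO4, 0.695 within regular MgSO4 and 0.0624 to 0.350 between media.

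**Figure D3:**
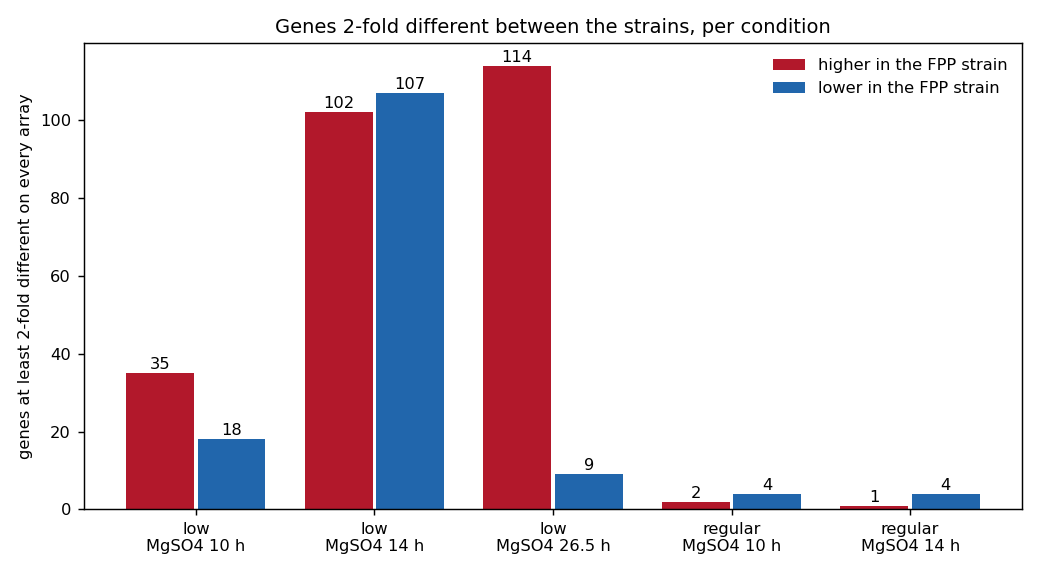
Number of genes at least 2-fold higher or lower in the FPP strain on every array of a condition (bars, gene counts). Counts run from 5 at regular 14 h to 209 at low 14 h, where scaling between arrays gives 46, below the 91 and 86 it gives at low 10 h and low 26.5 h, and the condition with 4 arrays had to meet the limit on all 4.

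The second comparison asked whether the strain difference depended on the medium, at 10 and 14 h. The largest coefficients, low minus regular, are given as values. rseA had 1.85 (SE 0.33), the antitoxin and toxin genes mqsA and mqsR had 1.72 (SE 0.20) and 1.71 (SE 0.24), and aroF had 1.59 (SE 0.21). gadE had -1.85 (SE 0.30), gadA -1.74 (SE 0.22), raiA -1.52 (SE 0.30) and gadB -1.48 (SE 0.29). A ratio can differ through either strain. By channel intensity, gadA low minus regular was 2.07 at 14 h and 1.43 at 10 h in the amorphadiene strain. In the FPP strain gadA gave 0.16 and -0.06. At the same times rseA gave -2.18 and -0.26 in the amorphadiene strain and 0.36 and 0.95 in the FPP strain. These 10 h values cross scan days and dyes. In lists, ribosomal proteins (0.75), sigma E (0.70), fatty acid synthesis (0.33), aromatic amino acid synthesis (0.29) and ATP synthase (0.29) had higher ratios in low MgSO4. Gad (-0.79), phage shock (-0.43), the RpoS general stress response (-0.31), glycolysis (-0.30), the Cpx envelope response (-0.30) and flagella (-0.16) had lower ones. The RpoS difference came from 14 h. Its means in low and regular MgSO4 were 0.22 and 0.20 at 10 h, and -0.29 and 0.34 at 14 h.

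By limma, 0 of 3946 genes passed for the medium (smallest adjusted p = 0.142), and 331 had an unadjusted p under 0.05 (221 higher, 110 lower); with all 5 conditions and no time term 9 passed (7 higher, 2 lower). The fit has 4 values and 1 residual degree of freedom. In simulated data with each gene's SD over all 5 conditions as spread, it recovered 0 of 66 genes changed 4-fold. That SD includes any real medium and time differences, so the simulated noise may exceed that of this fit. At 0.25 of that spread 66 of 66 were recovered. The list test, added after the data were seen, passed 11 of 42 lists by camera. Adjusted p by camera ran from 1.76e-28 for ribosomal proteins to 0.0407 for phage shock and aromatic amino acid synthesis. By camera with an estimated correlation 0 passed (adjusted p = 0.863). That form has only the 1 residual degree of freedom, with which almost no list could pass, so it cannot decide. Between 14 h arrays scanned on 1 day the mean difference was 0.92 for sigma E, 0.74 for ribosomal proteins, -1.0 for Gad, -0.64 for RpoS and -0.51 for glycolysis. Within that day phage shock had the opposite sign (0.12), and Cpx, fatty acid synthesis, ATP synthase, aromatic amino acids and flagella had -0.40, 0.40, 0.27, 0.24 and -0.13.

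The third comparison asked whether the strain difference changed from 10 to 14 h. Methionine synthesis genes had ratios 0.41 higher at 14 h, and the list's median was -0.12 at 10 h and 0.53 at 14 h in low MgSO4, where the dye orientation differs, and 0.06 and 0.15 in regular MgSO4. metE, the cobalamin-independent methionine synthase, stood at -1.10 and 0.53, and metF at -0.12 and 1.65; both were chosen after their values were seen. Phage shock (0.50), sigma E (0.30), respiratory chain (0.17) and iron acquisition genes (0.13) also had higher ratios at 14 h. Biofilm and indole-stress regulators (-0.53), Gad (-0.35), histidine synthesis (-0.33) and branched-chain amino acid synthesis (-0.18) had lower ones. Phage shock and Gad did so in low MgSO4 alone. Their means at 10 and 14 h were -1.45 and -0.28, and -0.28 and -0.99. In regular MgSO4 they were -0.35 and -0.53, and 0.09 and 0.16. The other lists moved the same way in both media, but less in regular MgSO4. Sigma E means at 10 and 14 h were 0.42 and 1.0 in low MgSO4 and 0.01 and 0.04 in regular MgSO4. Biofilm regulators had 0.27 and -0.73 in low MgSO4 and -0.18 and -0.24 in regular MgSO4. The phage shock values include pspA, which is saturated in the FPP strain at low 14 h.

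Single genes with the highest coefficients were the oligopeptide permease gene oppB (1.03), gapC_1 (0.97), ypeC (0.95) and marB (0.95). The lowest were waaY (-1.46) of lipopolysaccharide core synthesis, the regulator gene appY (-1.46), lpp (-1.23), which encodes the major outer membrane lipoprotein, and wbbH (-1.22). By limma, 0 of 3946 genes passed (smallest adjusted p = 0.998), with 77 at an unadjusted p under 0.05 (20 higher, 57 lower), fewer than the 197.3 given by chance. Camera, again added after the data were seen, passed 9 of 42 lists, from methionine synthesis (adjusted p = 2.77e-05) to the respiratory chain (adjusted p = 0.0416). By camera with an estimated correlation 0 passed (adjusted p = 0.942), but with 1 residual degree of freedom that form cannot decide. The 10 h and 14 h arrays of a medium were always scanned on different days, so time and scan day cannot be told apart; in low MgSO4 the dye orientation differs as well.

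Some genes were to be reported whatever their values. Of the native isoprenoid pathway, 0 of 11 genes passed over all genes tested by limma. Adjusted over the list alone dxs (0.43, SE 0.11), the entry enzyme of the methylerythritol phosphate pathway, did. No call is made for idi and ispA, the FPP synthase gene, since both idi channels and the ispA channel of the FPP strain were saturated at low 26.5 h; in the other 4 conditions idi stood at 0.22 to 0.33 and ispA at 0.32 to 0.84. pMBIS carries copies of both genes, and whether their RNA was measured by these spots was not examined here. lacZ averaged 0.10. The magnesium transporter gene mgtA was near 0 at low 10 h (0.03) and at -1.58 and -1.46 at low 14 and 26.5 h; its regulator gene phoP stood between -0.76 and 0.38. rpoS, the general stress sigma factor gene, was above 0 in low MgSO4 (0.18 to 0.96) and below 0 in regular MgSO4 (-0.74 and -0.26). marA had 0.66, 1.76 and 2.09 in low MgSO4 and 0.00 and 0.01 in regular MgSO4, and soxS ranged from -0.95 to 0.63.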

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

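All tests of glcF and yqjF, all tests of the phage shock genes, the tests of intensity and of single culture pairs for sigma E and ribosomal genes, and the list tests for medium and time were chosen after the result was seen. The tests by sign patterns and by scan day were set before.

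Turning the sign of some of the 5 conditions gives 16 patterns, too few for a share under 0.05. For genes the real signs gave 2 past the threshold and the highest other pattern 0, so 1 of 16 patterns reached the real count. For lists the real signs gave 7 and the highest other 10, and 10 of 16 patterns reached 7. The pattern that sets low against regular MgSO4 gave 9 lists, and the pattern that sets low 10 h, with its opposite dye, against the rest gave 7; between 14 h arrays of 1 scan day the low minus regular difference was 0.92 for sigma E and -1.0 for Gad.

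glcF and yqjF were higher in the FPP strain in 5 of 5 conditions. A dye bias of these spots would turn their sign in the condition with opposite dyes, where the smaller ratio was 1.88. More RNA of the whole operon would raise their neighbours, whose means had a median of -0.064 (6 genes, SD 0.15), below the bound of 0.80. A difference between the clones grown, or binding of plasmid RNA to these spots, may account for the ratios and stays open, since each condition had 1 biological replicate and no probe sequences were used here. The biological difference named by the design, FPP accumulation, also stays open, and it cannot be told apart from amorphadiene production in the other strain.

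Sigma E and ribosomal protein genes had higher ratios in low MgSO4. Against a bias with intensity, their medians exceeded the upper 2.5% point of matched random lists by at least 0.21 in the 3 low conditions. Against scan day, the smaller of both differences was 0.74 between 14 h arrays of 1 day. A difference between single pairs of cultures other than the medium could also give this and cannot be told apart from the medium: each low condition had 1 biological replicate, and whether the 3 share cultures is not given. An effect of the medium stays open too.

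The phage shock genes were low at low 10 h, with a list mean of -1.45, and less so in regular MgSO4, with -0.35 at 10 h and -0.53 at 14 h. A dye bias would put the list above 0 in the conditions with the other orientation; over the 2 of these with no saturated gene its mean was -0.44 (SD 0.13), and over all 4, with saturated genes at low 14 and 26.5 h, -0.28 (SD 0.23). Channels named the wrong way round would give a correlation across genes with low 26.5 h below 0, and Pearson's r was 0.418. Saturation hiding a like difference at 26.5 h would leave unsaturated spots low, but the median over 3 genes with 10 such spots was 0.11; a first form of this test used genes that were not low and could decide nothing. Differences between cultures may contribute and were not tested. Over time the list differed by 0.50, 14 h minus 10 h, by camera (adjusted p = 0.0239, and adjusted p = 0.942 with an estimated correlation). The form with an estimated correlation has 1 residual degree of freedom and cannot decide. Time cannot be told apart from scan day, and in low MgSO4 the dye orientation differs too. Whether the times share cultures is not given.

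Other results are given as values. On the fourth regular 14 h array the MarA-SoxS-Rob list had a mean log2 ratio of 0.025, apart from the other 3 arrays at 0.17 to 0.18; 90 such values were examined and 1 stood apart, where chance alone marks about 1 in 20. That array had the lowest signal.

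The strain difference of 11 lists differed between media by camera, low minus regular: ribosomal proteins 0.75, sigma E 0.70, fatty acid synthesis 0.33, aromatic amino acids 0.29, ATP synthase 0.29, flagella -0.16, Cpx -0.30, glycolysis -0.30, RpoS -0.31, phage shock -0.43 and Gad -0.79. For 9 lists it differed between times, 14 h minus 10 h: phage shock 0.50, methionine 0.41, sigma E 0.30, respiratory chain 0.17, iron acquisition 0.13, branched-chain amino acids -0.18, histidine -0.33, Gad -0.35 and biofilm regulators -0.53. In regular MgSO4 the phage shock mean was -0.35 at 10 h and -0.53 at 14 h and the Gad mean 0.09 and 0.16, so the sign of both differences came from low MgSO4. By camera with an estimated correlation 0 lists passed in either comparison (adjusted p = 0.863 and adjusted p = 0.942). With 1 residual degree of freedom almost none could, so this decides nothing.

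For 6 named genes all 6 low MgSO4 arrays went opposite to all 6 regular arrays, a difference that was not tested at this level. Arrays of a condition are technical repeats. mqsA, mqsR, gadA and gadB were named for their medium coefficients and mltD for its ratio at low 26.5 h, so the split is partly built in. The low minus regular means were 1.70 for mltD, 1.69 for mqsR, 1.62 for mqsA, 0.92 for rpoS, -1.80 for gadB and -1.87 for gadA.

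Of 1005 positions named empty or blank, 789 were above background on at least 6 of 12 arrays. They entered no comparison.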

How the results depend on the processing

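The fits to a single medium, the fits without the later-scanned arrays and the list tests for medium and time were chosen after the data were seen. No paired analysis was possible because replicate numbers only name technical arrays, which were averaged per condition. glcF passed in 27 of 33 alternatives (log2 0.93 to 2.10) and npr in 23 of 33 (0.50 to 0.84). Over all conditions, 2 genes became 1 with median centring, print-tip loess or the brightest spot, and 11 with scaling between arrays (7 higher, 4 lower). With 12 arrays and condition as a random block they became 144 (91 higher, 53 lower, correlation 0.713). With scan day as a random block they became 26 (8 higher, 18 lower, correlation 0.0831). That fit had 6 values, since regular 14 h entered once per scan day. A dye term, or turning the sign of low 10 h, left 0. Low MgSO4 alone gave 49 (43 higher, 6 lower) and regular alone, with 2 values per gene, 754 (315 higher, 439 lower). Leaving out single conditions or arrays gave 0 to 2. The medium comparison gave 9 genes without a time term over 5 conditions. Called lists numbered 2 with fry. With an estimated correlation they numbered 0 in all 3 list tests, where few residual degrees of freedom left little power. Sigma E and ribosomal proteins passed in 29 of 31 alternatives each, MarA-SoxS-Rob in 30, curli and fimbriae in 28, Gad in 27, iron and fatty acid synthesis in 22 each. For low against regular, phage shock passed in 11 of 22 and aromatic amino acids in 12 of 22.

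Counts of 2-fold genes at low 10 h, low 14 h, low 26.5 h, regular 10 h and regular 14 h were 214, 646, 313, 68 and 30 at 1.5-fold, and 11, 33, 39, 0 and 0 at 3-fold. Scaling gave 91, 46 and 12 at low 10 h, low 14 h and regular 10 h. At regular 10 h the mean over arrays gave 11, and leaving out an array 10 to 16. At regular 14 h no background correction gave 2, the brightest spot 3, the mean over arrays 9, and the first 2 arrays alone 9. Fold limits and fewer arrays change these counts by construction; for the others the cause was not tested. The 14 h minus 10 h comparison without low 10 h gives values with no test. No called value changed sign in the alternatives it was tried in. The phage shock difference between media did within 1 scan day (0.12). The list test was not run on regular MgSO4 alone. There the means at 10 and 14 h opposed the call for ribosomal proteins (-0.15 and -0.17), Gad (0.09 and 0.16) and fatty acid synthesis (-0.08 and -0.06). The other called lists kept their sign there, but sigma E was near 0 (0.01 and 0.04), with medians inside the range of matched random lists. On the fourth regular 14 h array 31.8% of gene spots were marked bad and 3219 genes had a value; all 4 arrays had one for 3049 genes, and for 4284 with marked spots kept.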

Other observations

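The magnesium and sulfate tests were set before their results were seen; the genes named here from lists were chosen after their values were seen.

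Some lists without a call by camera over all conditions held single genes past the test adjusted over the list alone, with 0 over all genes tested by limma. In the nitrogen limitation list these were 3 of 22, all lower in the FPP strain: glnK (-0.68, SE 0.13), a signalling protein of ammonium uptake, argT (-0.65, SE 0.10), a binding protein for basic amino acids, and the ammonium channel gene amtB (-0.48, SE 0.07). The list's mean was -0.04 and its median 0.00, and camera gave an adjusted p of 0.547. Among outer membrane porins and related proteins 3 of 9 were lower, ompT (-0.52), ompC (-0.48) and ompW (-0.34), with camera at adjusted p = 0.177 and fry at adjusted p = 0.00233. Of the biofilm and indole-stress regulators, ymgA (-0.77) and ymgC (-0.65) were lower and bhsA (1.02) was higher. Single genes elsewhere were ahpC (0.38) of the peroxide response, otsB (0.43) of trehalose synthesis, osmE (0.58) and sodC (0.26) of the RpoS list, cpxA (0.36), cyoE (0.64), nuoK (-0.31), dinF (-0.40), polB (-0.28), ugpB (-0.56), malQ (-0.38) and glpA (-0.83). For yrbL of the PhoPQ list no call is made, because its FPP channel is saturated at low 26.5 h.

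Amino acid synthesis lists went different ways over time in low MgSO4, where the dye orientation at 10 h is opposite to that at later times. The aromatic list had similar medians at 10, 14 and 26.5 h (0.11, 0.17 and 0.11). Medians at 10, 14 and 26.5 h were 0.10, -0.39 and -0.26 for the histidine list and 0.00, -0.28 and -0.15 for the branched-chain list, against -0.12, 0.53 and 0.49 for the methionine list and -0.07, 0.26 and 0.35 for the arginine list. The methionine pathway repressor gene metJ stood at -0.35, 1.30 and 1.01 at 10, 14 and 26.5 h, tyrA of tyrosine synthesis at 0.91, 2.05 and 1.56, and argC of arginine synthesis at 0.22, 0.87 and 1.62. In regular MgSO4 metJ had 0.41 and 0.53, tyrA -0.04 and 0.24, and argC 0.07 and -0.15. These values come from single pairs of cultures and carry no test.

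Which medium held less magnesium was examined through channel intensities of a single strain, since the protocol's concentrations oppose the medium names. If the medium named low held less magnesium, the PhoPQ regulon, which responds to low magnesium, would be higher there. In the amorphadiene strain at 14 h, on arrays of the same scan day and dye, mgtA was 5.29 higher on the log2 scale in the medium named low, phoP 3.54 and mgrB 2.00, and the list's median difference was 1.73, against an upper bound of 0.32 for random lists. The FPP strain gave 3.88 for mgtA and 1.89 for the list. At 10 h, across scan days and dyes, the amorphadiene strain gave 2.98 for mgtA, 0.19 for mgrB, -0.88 for yrbL and 0.98 for the list (upper bound 0.53). The shift at 14 h was not particular to PhoPQ: ribosomal proteins (0.96), Gad (0.89) and sigma E (0.68) also exceeded their bounds. In the FPP strain these 3 lists gave 1.82, 0.06 and 1.40, and Gad stayed below its bound. The mgtA and list values are consistent with less magnesium in the medium named low, as a hypothesis from 1 biological replicate per condition. Sulfate low enough to be limiting would raise the sulfate assimilation and sulfonate use lists. Their larger median was 0.012 (percentiles 17.2 and 9.10 among random lists), which argues against limiting sulfate in the medium named low. A lower but sufficient sulfate level need not raise these lists, so the test cannot decide on it.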
